A study of Gallus gallus with 58 samples.

How the data were processed

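Gonads of day 19 chicken embryos (Gallus gallus) were measured in 2 assays, each with 29 libraries. Embryos had been injected on day 6 of incubation, through the egg, with an oil emulsion alone (vehicle) or with 20 µg per egg of 17α-ethynylestradiol (EE2), a synthetic estrogen, in 50 µL of that emulsion. Genetic sex (ZZ in males, ZW in females) and a feminization score of the gonad come from the labels: vehicle females and EE2 females have score 3, vehicle males score 0 and EE2 males score 1 or 2. RNA sequencing covered 5 vehicle females, 5 vehicle males, 2 EE2 females and 17 EE2 males (10 of score 1 and 7 of score 2). MBD sequencing, in which methylated DNA is captured by a methyl-CpG binding domain protein before sequencing, covered 5 vehicle females, 4 vehicle males, 2 EE2 females and 18 EE2 males (11 of score 1 and 7 of score 2). RNA and DNA came from the same extraction kit, and both kinds of library were read as single 50-nt SOLiD reads, per the labels' protocols. Sample names give separate embryos. Some names carry the prefix CH, whose meaning is not given in the sources used here. The prefix is on no vehicle library, on both EE2 females in each assay, on 7 of the 17 EE2 male RNA libraries and on 8 of the 18 EE2 male MBD libraries. One EE2 male is scored 1 in its characteristics while its name carries F2, as names of EE2 males scored 2 do; the characteristics were followed.

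The RNA gene values deposited by the authors are a normalized signal per gene, described as normalized CPM, with edgeR 3.28.1 named in the submitters' processing notes. They are called normalized CPM here. The columns sum to 932560.1 to 1119003.5, as library sizes scaled by factors such as TMM would give, while the design had assumed plain CPM. The deposited repeat values, TMM-normalized per the sheet's name, are the same kind of normalized signal for each copy of a repeat, with 698947 copies of 11336 repeat names, 105541 of which had reads in no library. The MBD values deposited by the authors are a score with no stated unit per 100-bp window, over 10319019 windows. The values run from 0 to 1 in every library in steps that differ between libraries, so that neither their scale nor their share of zeros compares directly. The aligner, the read counter, its use of strand, its treatment of reads that match several copies, the genome builds of the gene and MBD tables and the steps that made the MBD score are not given in the sources used here. Repeat coordinates are printed as deposited, and their sequence names match those of GRCg6a. MBD coordinates are printed as deposited, on an unstated build, and no coordinates were carried from either table to the other.

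Within each RNA library all values were whole multiples of the value of 1 read (100% of values whole within a tolerance of 0.1 reads), so read numbers were recovered. Gene libraries held 3364941 to 46388648 reads (median 6079642), and repeat libraries 507768 to 4234647 reads (median 846862). No depth can be recovered from the MBD score. The share of windows above 0 was taken per library instead.

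RNA genes were tested with limma 3.58.1 (R 4.3.3) on log2(normalized CPM + 0.5) with an intensity trend, in a fit of all 29 libraries with 4 groups, over 4448 of 5211 genes with a mean of at least 1 normalized CPM. The score comparison used the same fit with EE2 males split by score. Tests were two-sided with Benjamini-Hochberg adjustment, and genes with adjusted p under 0.05 were called. Adjusted p-values of genes, repeat copies and MBD tiles are from limma unless another tool is named. Fold changes are on the log2(value + 0.5) scale, which understates the change of low genes. Repeat copies were tested in the same way (147590 copies with a mean of at least 1). MBD windows were averaged in 1-kb tiles, and 499509 tiles whose mean was above the median of tiles with any signal (0.12) were tested on log2(score + 0.0183). Because the MBD libraries differ in scale, the planned quantile-normalized fit is reported beside the fit of the scores as deposited. Recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0. Other steps used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

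Gene symbols were matched to the symbols of the GRCg7b annotation for their chromosome class only (4587 of 5211 matched, 4382 autosomal, 203 on Z and 1 on W). The female position of a library places it between the mean of vehicle males (0) and that of vehicle females (1), by projection over sex-biased autosomal genes. Vehicle libraries were placed with themselves left out. Single values per library were compared with exact permutation tests, or with 100000 resamples where groups were larger. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison.

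Groups, comparisons, filters, gene lists, named genes and most alternatives were chosen before the data were examined. The named genes of a comparison are the 8 called genes with the largest rise and the 8 with the largest fall, among those with a symbol and a mean of at least 5 in the higher group. To these were added up to 4 called members of each list and, whatever their test, DMRT1, SOX9, AMH, FOXL2, CYP19A1, ESR1, STRA8 and DDX4; STRA8 was not analysed here, and a few genes that the rule names are not reported here. For repeats the 5 called copies per direction with the largest log2 fold change and a mean of at least 5 in the higher group were taken, and for MBD the 5 tiles with the smallest p per direction and the 100000-bp bin of Z with most called tiles. The 23 tested lists, with tested of all members, were testis genes (9 of 14), ovary genes (9 of 15), germ cells (7 of 23), oocyte (7 of 20), steroidogenesis (13 of 22), estrogen targets (12 of 25), hedgehog (3 of 12), TGF-beta (12 of 23), Wnt (14 of 26), DNA methylation (6 of 18), piRNA pathway (3 of 24), proliferation (16 of 22), collagen and matrix (17 of 22), Leydig cells (5 of 8), surface epithelium (7 of 15), Müllerian duct (6 of 11), mesonephros (4 of 19), adrenal (4 of 13), erythroid (10 of 20), immune (12 of 20), endothelium (6 of 13), muscle (9 of 14) and neural (8 of 12). Meiosis had 1 tested gene, and W-linked genes had 0 genes in the table.

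Fits were tested on simulated data built from the real means and depths. Among 2-fold changes limma recovered 74.7% for the sex difference, 84.3% for EE2 in males, 70.4% for EE2 in females, 87.8% for EE2 males against vehicle females and 89.3% for the score. For 4-fold changes the shares were 95.4%, 96.5%, 84.3%, 94.3% and 97.6%. Repeat copies changed 16-fold were recovered in 68.6%, 93.2%, 38.7%, 86.8% and 81.5%, and those changed 4-fold in 16.3%, 31.2%, 11.5%, 28.6% and 43.2%. MBD tiles changed 4-fold were recovered in 5%, 6%, 4%, 10% and 9% as deposited and in 23%, 29%, 35%, 39% and 47% after quantile normalization, which in the EE2 female comparison also called 437 unchanged tiles. A position of 0.5 put into 600 of 4440 genes came back as 0.49.

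Alternatives were other pseudocounts and filters, quantile normalization, only the groups compared, no CH libraries, a 2-fold threshold, the EE2 male with conflicting labels moved or left out, each library left out, edgeR and DESeq2, an estimated correlation for lists, sex chromosomes left out, other forms of the position, other MBD tile sizes, and the replicate number as a block. Added after the data had been seen were the prefix as a covariate, the share of MBD windows as a covariate, MBD scores without a log, combinations of quantile normalization with no CH libraries, 5-kb tiles or both, MBD libraries under 15% of windows left out, a position from Z genes, the W share of repeat reads without CH libraries, and sums per repeat name. Counting error alone is covered by the floor of 3 reads used for genes with no reads in a group.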

Results

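Messenger and repeat RNA and captured methylated DNA were measured in gonads of day 19 chicken embryos after injection of vehicle or EE2. The design asks how the gonads of the sexes differ, what EE2 does to the gonads of genetic males and females, how far EE2 males come to resemble females, and whether males given feminization score 2 differ from those given score 1. Gene reads per RNA library ran from 3364941 to 46388648 with a median of 6079642. Every vehicle library lacks the name prefix CH and both EE2 females carry it, so that prefix and treatment cannot be told apart within females. In EE2 males, 1946 of 4448 genes differed between the 7 CH and the 10 other libraries (1075 higher and 871 lower with CH), so several values are also given without CH libraries. The replicates of a group differed by more than the sampling noise of their reads in all 87 pairs compared.

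Vehicle female and vehicle male gonads differed in enzymes and transcription factors of sex differentiation. CYP19A1 encodes aromatase, which turns androgens into estrogens. It stood at 4980 ± 554 normalized CPM in vehicle females (SD, n = 5) and 6.84 ± 4.03 in vehicle males (SD, n = 5), a log2 difference of -9.55 (SE 0.56, adjusted p = 5.9e-13). FOXL2, the forkhead factor of ovarian granulosa cells, was at 7.97 ± 2.71 in females and had no reads in any vehicle male, so that females were at least 11.7-fold higher against a floor of 3 reads per male library. SOX9, the factor of Sertoli cell differentiation, was at 32.2 ± 6.16 in males and 2.92 ± 1.18 in females, a log2 difference of 3.32 (SE 0.33, adjusted p = 8.9e-09). In all, limma called 1689 of 4448 genes, with 958 higher in males and 731 higher in females (239 and 322 among those differing at least 2-fold).

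The remaining genes fixed for every comparison followed the sexes in part. AMH, the hormone that regresses Müllerian ducts, was higher in males by 1.94 (SE 0.41, adjusted p = 0.00039), with 2610 ± 561 against 710 ± 280 normalized CPM. DMRT1, the Z-linked testis factor, was higher by 1.32 (SE 0.24, adjusted p = 7.3e-05). ESR1, an estrogen receptor, was lower in males by a log2 value of -1.29 (SE 0.2, adjusted p = 1.2e-05). The germ cell helicase DDX4 had a difference of 0.74 and did not pass (adjusted p = 0.12).

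SMYD1, a lysine methyltransferase of muscle cells, was at 151 ± 46.4 normalized CPM in vehicle females and 0.859 ± 0.494 in vehicle males (log2 -6.82). The calcium-binding protein CALB1 differed by -5.71, the interleukin-7 receptor IL7R by -4.84, the receptor phosphatase PTPRZ1 by -4.66, the interferon-inducible ISG12-2 by -4.65 and the membrane glycoprotein EMB by -4.51. TH, the rate-limiting enzyme of catecholamine synthesis, varied widely among vehicle females (151 ± 135 against 0.559 ± 0.282 in males, log2 -5.64, SE 1.7, adjusted p = 0.0097). Male-higher genes were led by the organic anion transporter SLCO4A1, at 472 ± 67.5 against 11.6 ± 3.57 (log2 5.33, adjusted p = 8.7e-10), and by ALDH1A1, which makes retinoic acid and lies on Z, at 1750 ± 249 against 59.2 ± 45.8 (log2 5.13). They also held the homeobox gene MNR2 (4.09), the collagen chain COL9A2 (4.02), KCNMB1, a potassium channel subunit of smooth muscle (3.63), and the nuclear receptor NR5A2 (3.62). INHA, the alpha chain of inhibin, was at 10.6 ± 3.01 in vehicle males and had only 2 reads over all vehicle females, so no fold is given (adjusted p = 1.6e-07).

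**Figure D1:**
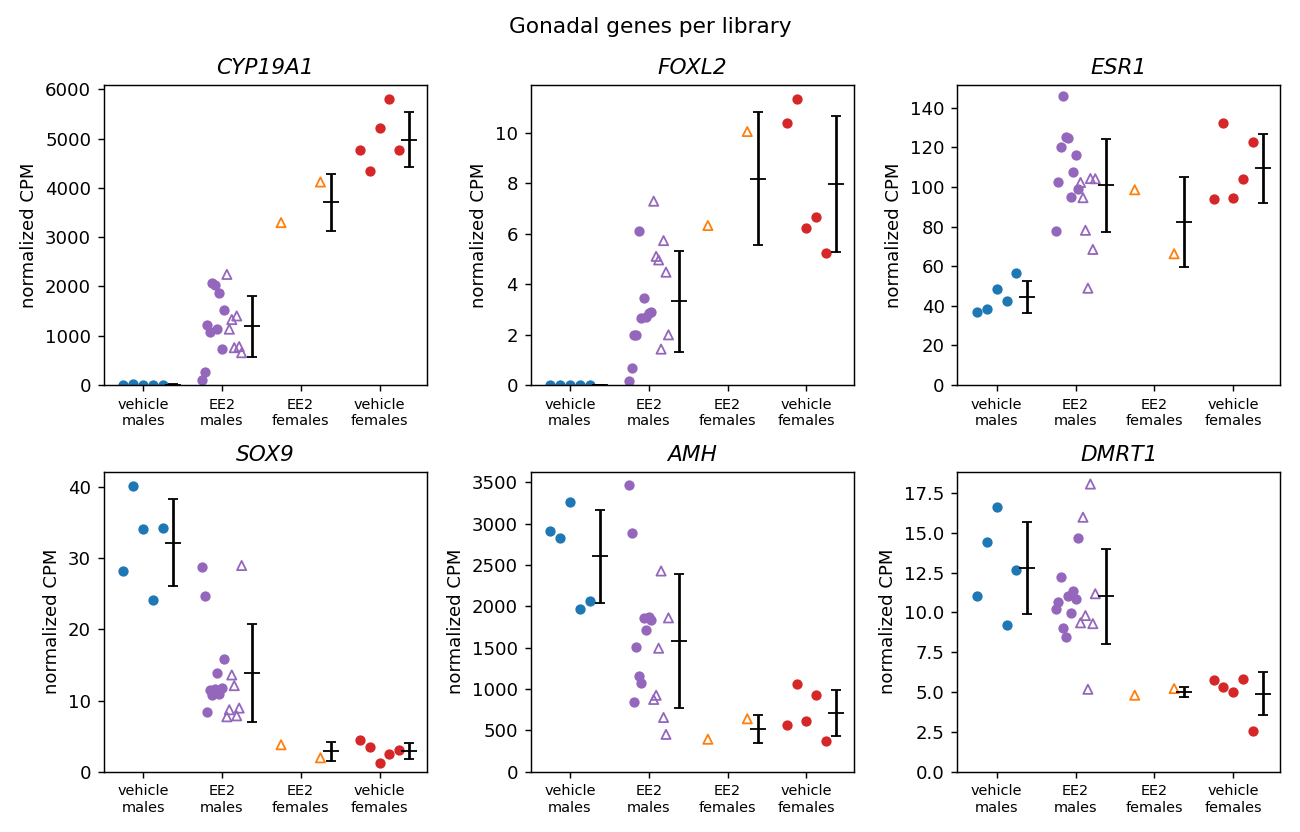
Normalized CPM per library (y axes) of CYP19A1, FOXL2, ESR1, SOX9, AMH and DMRT1 in the 4 groups of RNA libraries (x axes): blue vehicle males, purple EE2 males, orange EE2 females and red vehicle females, with open triangles for name prefix CH and bars for the mean ± SD. CYP19A1 of EE2 males (mean 1190) lies between vehicle males (6.84) and vehicle females (4980), while DMRT1 of EE2 males (11.0) lies near vehicle males (12.8).

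By gene list, 6 of 23 lists were called with the preset correlation, and only the ovary list held with an estimated correlation (adjusted p = 0.0287). Its tested members were lower in males in 8 of 9 cases (8 also when adjusted over the list alone), with a median log2 of -1.29 (adjusted p = 5.6e-05). Besides CYP19A1, FOXL2 and ESR1 they included the homeobox gene LHX2 (-1.40), which did not pass after quantile normalization (-0.88, adjusted p = 0.056). WNT4, which acts in ovary formation, was called at -0.65 but not without vehicle female 4 (-0.53, adjusted p = 0.073), without vehicle male 4 (-0.55, adjusted p = 0.069) or after quantile normalization (-0.53, adjusted p = 0.077). Oocyte genes were lower in males for 4 of 7 (adjusted p = 0.00878; adjusted p = 0.19 with an estimated correlation), among them the egg coat genes ZP1 (-4.25), ZPD (-3.63) and ZP3 (-3.01) and the oocyte growth factor GDF9 (-1.34). Proliferation genes were higher in males for 14 of 16 (median 0.63, adjusted p = 0.000102; adjusted p = 0.365 with an estimated correlation), such as the cyclin CCNA2 (0.91), the kinases CDK1 (0.84) and PLK1 (0.82) and the kinetochore gene NDC80 (0.98). Collagen and matrix genes were higher for 9 and lower for 1 of 17 (10 and 1 adjusted over the list alone, adjusted p = 0.0135; adjusted p = 0.49 with an estimated correlation), with COL6A1 at 1.56, COL6A2 at 1.20 and COL6A3 at 1.15, and the matrix protein THBS1 the lower one. The surface epithelium list had 3 of 7 lower (adjusted p = 0.0357; adjusted p = 0.19 with an estimated correlation), with the keratin KRT19 (-1.84) and WT1 (-0.75). Endothelial genes had 3 of 6 lower (adjusted p = 0.0387; adjusted p = 0.365 with an estimated correlation), including the VEGF receptors KDR (-1.57) and FLT1 (-1.12).

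Lists that were not called still held members that differed between vehicle males and females. Testis genes were higher for 5 and lower for 1 (6 and 1 adjusted over the list alone, adjusted p = 0.174). The hedgehog receptor PTCH1, on Z, was higher by 2.57 (SE 0.22, adjusted p = 5.9e-10), with GLI2 at -0.36 in a list with 1 in each direction (adjusted p = 0.337). Steroidogenesis had 2 higher and 5 lower (4 and 5 adjusted over the list alone, adjusted p = 0.242), with the cholesterol carrier STAR at -2.05 and the luteinizing hormone receptor LHCGR at -1.90. Wnt genes had 1 higher and 6 lower (adjusted p = 0.111), with WNT5A at 1.97 and the antagonist DKK3 at -2.06. TGF-beta genes had 3 in each direction (adjusted p = 0.896), with BMP4 at -2.17. Muscle genes had 4 higher and 2 lower (adjusted p = 0.175), with the smooth muscle myosin MYH11 at 2.29 and TAGLN at 2.99. Germ cell genes had 3 higher and 1 lower (adjusted p = 0.197), with the receptor KIT at 1.48, and DNA methylation genes 2 higher (adjusted p = 0.561), with the methyltransferase DNMT3B at 0.72. The meiosis gene MND1 was higher by 0.70 (adjusted p = 0.012). Of the markers of other cells, neural genes had 1 higher and 4 lower (1 and 5 adjusted over the list alone, adjusted p = 0.25), with the neuronal genes STMN2 at -3.67 and SNAP25 at -2.72, and adrenal genes 2 lower (adjusted p = 0.15). Immune and mesonephros genes had 2 lower each (adjusted p = 0.208 and 0.119), erythroid genes 1 lower (0 over the list alone, adjusted p = 0.242), and piRNA, Leydig and Müllerian genes 1 in each direction (adjusted p = 0.87, 0.87 and 0.83; for Müllerian genes 0 higher and 1 lower over the list alone). Estrogen targets had 1 higher and 2 lower (0 and 1 adjusted over the list alone, adjusted p = 0.25). Median, mean and test differed in sign for the TGF-beta and Leydig lists.

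EE2 moved male gonads toward the female pattern for aromatase and many ovary genes. CYP19A1 rose from 6.84 ± 4.03 normalized CPM in vehicle males (SD, n = 5) to 1190 ± 616 in EE2 males (SD, n = 17), a log2 change of 7.21 (SE 0.45, adjusted p = 3e-12) and of 7.10 in EE2 males without CH (adjusted p = 1.7e-08). FOXL2 was at 3.31 ± 2.0 in EE2 males and at 0 in vehicle males, at least 4.87-fold higher against the same floor. ESR1 rose by 1.15 (SE 0.16, adjusted p = 7.8e-06) and DDX4 by 1.15 (SE 0.3, adjusted p = 0.0032), while SOX9 fell by 1.29 (SE 0.27, adjusted p = 0.00054), from 32.2 ± 6.16 to 13.9 ± 6.89. Without CH libraries these changes were 1.31, 1.19 and -1.17 (adjusted p = 2.8e-07, 0.0032 and 0.0013). The rise of DDX4 was not a move toward the female level. DDX4 ran from 13.08 to 64.17 normalized CPM in vehicle females, 38.72 to 76.17 in vehicle males and 61.02 to 257.3 in EE2 males. DMRT1 had a difference of -0.22 that did not pass (adjusted p = 0.37), with 12.8 ± 2.88 in vehicle and 11.0 ± 2.99 in EE2 males.

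AMH was called at the edge of the threshold (log2 -0.87, SE 0.33, adjusted p = 0.036), with 2610 ± 561 normalized CPM in vehicle males and 1580 ± 807 in EE2 males. It did not pass without vehicle male 1, 2 or 3 (-0.83, -0.84 and -0.79, adjusted p = 0.081, 0.075 and 0.099), without CH libraries (-0.61, adjusted p = 0.088), after quantile normalization (-0.72, adjusted p = 0.075), in edgeR (-0.72, adjusted p = 0.064) or in DESeq2 (-0.71, adjusted p = 0.068).

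In all, 1669 genes were called in males, 799 higher and 870 lower with EE2 (241 and 92 among those changed at least 2-fold, and 955 and 849 in DESeq2). Of the 1708 genes called without CH libraries, 1324 were called in the same direction in the pooled fit. The largest rises after CYP19A1 were those of the gallinacin GAL10, an antimicrobial peptide (4.34), CALB1 (4.12), the chemokine CXCL14 (4.03), ISG12-2 (4.01), the adhesion molecule CNTN2 (3.97), EMB (3.91) and PCK1 of gluconeogenesis (3.76). GAL10 was very uneven, with 4920 ± 6820 in EE2 males, and was not called without vehicle male 4 (3.45, adjusted p = 0.055) or without CH libraries (2.98, adjusted p = 0.063). Among the largest falls were those of COL9A2 (-2.32), INHA (-2.31), C21H1orf187 (-2.21), the homeobox gene MEOX2 (-2.20), SLCO4A1 (-2.20), MNR2 (-2.14) and KCNMB1 (-2.08). KCNMB1 went from 165 ± 17.5 to 48.2 ± 28.8 normalized CPM and MEOX2 from 222 to 54.1.

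Of the 23 lists, 3 were called in males, and the ovary list held with an estimated correlation (adjusted p = 0.0207). Its members rose in 8 of 9 cases (8 adjusted over the list alone, median 1.18, adjusted p = 2.45e-05), including LHX2 (1.39) and FST (1.18), an activin-binding protein. Surface epithelium genes rose for 5 of 7 (adjusted p = 0.0201; adjusted p = 0.114 with an estimated correlation), with KRT19 at 1.15 and WT1 at 0.54. Oocyte genes rose for 4 and fell for 1 of 7 (adjusted p = 0.0401; adjusted p = 0.245 with an estimated correlation), with ZPD at 3.06, ZP1 at 2.66 and GDF9 at 1.37. Muscle genes fell for 4 of 9 (6 over the list alone) without a call for the list (adjusted p = 0.0752), with MYH11 at -1.60, TAGLN at -1.59 and ACTA2 at -0.95. Collagen and matrix genes rose for 1 and fell for 8 (1 and 9 over the list alone, adjusted p = 0.0796), with LUM at -0.87 and COL6A1 at -0.79. Wnt genes rose for 7 and fell for 2 (adjusted p = 0.0796), with WNT9A at 1.48, the factor TCF7 at 1.19 and DKK3 at 1.15. Testis genes went both ways, 3 and 3 (adjusted p = 0.785), with FGF9, a growth factor of testis formation, at 1.08. Steroidogenesis also went both ways, 3 and 3 (adjusted p = 0.478), with STAR at 1.25 and the steroidogenic factor NR5A1 at -0.84. Among germ cell genes 3 rose and 1 fell (adjusted p = 0.333); DAZL, an RNA-binding protein of germ cells, was called at 0.90 but not without vehicle male 4 (0.72, adjusted p = 0.069). PIWIL1, of the piRNA pathway, rose by 1.23, PTCH1 fell by 1.32, KDR rose by 1.58 and MND1 fell by 0.62.

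Markers of nerve and adrenal cells stood beside these groups. Neural genes rose for 4 and fell for 1 of 8 in EE2 males (median 0.96, adjusted p = 0.333), with STMN2 at 2.90, SNAP25 at 2.05 and the RNA-binding ELAVL4 at 1.25. STMN2 and SNAP25 were not called with the prefix as a covariate (1.73 and 1.32, adjusted p = 0.079 and 0.061). Of the adrenal genes TH alone was called (3.70, adjusted p = 0.033; list median 1.06, adjusted p = 0.447), with 141 ± 352 normalized CPM, and it was not called without any of the 5 vehicle males (3.56 to 3.81, adjusted p = 0.055 to 0.072) or without CH libraries (1.71, adjusted p = 0.15). Estrogen targets rose for 4 and fell for 2 of 12 (4 and 3 over the list alone, adjusted p = 0.413), with IGF1 at 1.01 and the vitellogenin VTG2 at -0.50. Proliferation genes fell for 4 of 16 (adjusted p = 0.191), with KIF11 at -0.77 and NDC80 at -0.75. TGF-beta genes rose for 4 and fell for 3, with BMP4 at 1.65. Median, mean and test differed in sign for testis, hedgehog, TGF-beta and immune genes.

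EE2 males were set against vehicle females to see what still separated them. CYP19A1 remained lower in EE2 males by a log2 value of -2.34 (SE 0.45, adjusted p = 0.00025), FOXL2 by -1.33 (SE 0.38, adjusted p = 0.0091) and SMYD1 by -3.90, with 12.5 ± 11.9 against 151 ± 46.4 normalized CPM. SOX9 was higher by 2.03 (adjusted p = 1.6e-06), DMRT1 by 1.09 (adjusted p = 9.4e-05) and DDX4 by 1.90 (adjusted p = 1.9e-05). ESR1 showed a difference of -0.15 that did not pass (adjusted p = 0.54), with 101 ± 23.4 in EE2 males and 110 ± 17.4 in vehicle females. Without CH libraries the values were -2.45 for CYP19A1, -1.65 for FOXL2, 2.15 for SOX9, 1.93 for DDX4 and 0.02 for ESR1. AMH was called at 1.07 (adjusted p = 0.015), but not without vehicle female 5 (0.86, adjusted p = 0.071).

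A total of 1332 genes were called, 777 higher and 555 lower in EE2 males than in vehicle females. Of the 1595 called without CH libraries, 1068 were called in the same direction in the pooled fit. The higher genes were led by ALDH1A1 (3.73), SLCO4A1 (3.13), LIX1 on Z (2.55), the Wnt inhibitor WIF1 (2.21), the folate receptor FOLR1 (2.14), the protocadherin PCDH15 (2.06) and SALL3 (2.05), a zinc finger factor. The lower ones, after SMYD1 and CYP19A1, were ZP3 (-2.60), DYDC1 (-2.17), FET1 (-1.81), the sialyltransferase ST8SIA3 (-1.70), the glutamate receptor GRIA4 (-1.69) and the muscarinic receptor CHRM2 (-1.66). ST8SIA3 was not called by edgeR (-1.18, adjusted p = 0.11) or DESeq2 (-1.23, adjusted p = 0.094).

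The 2 lists called in this comparison were both higher in EE2 males, and neither held with an estimated correlation. Proliferation genes were higher for 11 of 16 (12 over the list alone, adjusted p = 0.000296; adjusted p = 0.503 with an estimated correlation), with CCNA2 at 0.80 and the replication genes MCM5 at 0.80 and MCM3 at 0.78. Germ cell genes were higher for 4 of 7 (adjusted p = 0.00468; adjusted p = 0.503 with an estimated correlation), namely DDX4, DAZL (1.48), KIT (1.46) and ASZ1 (1.24). Testis genes were higher for 6 of 9 without a call for the list (adjusted p = 0.0676), including TESC (0.96). Ovary genes were higher for 1 and lower for 3 (adjusted p = 0.242), with WNT4 at -0.77. Collagen and matrix genes were higher for 8 and lower for 1 (9 and 1 over the list alone, adjusted p = 0.0922), with tenascin, TNC, at 1.73. Steroidogenesis had 3 higher and 5 lower (adjusted p = 0.281), with NR5A2 at 1.84, HSD17B4 at 1.13 and LHCGR at -1.40. Immune genes had 4 lower (5 over the list alone, adjusted p = 0.152), neural genes 2 higher (adjusted p = 0.812) and adrenal genes 0 called (median -1.31, adjusted p = 0.258). Median, mean and test differed in sign for estrogen targets, Wnt, surface epithelium and muscle.

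Of the 1689 genes that differed between vehicle sexes, 973 (57.6%) changed toward the female level in EE2 males, 23 changed away from it and 693 did not pass, and 756 (44.8%) still differed from vehicle females. Autosomal genes moved in similar shares whichever sex was higher: 391 of 645 female-higher genes (60.6%) and 454 of 751 male-higher genes (60.5%). Genes on Z that were higher in males moved in 31 of 114 cases (27.2%), 11 moved away, and 102 (89.5%) still differed from vehicle females (Fisher's exact test against autosomal male-higher genes, odds ratio 0.245, p = 3.06e-11, over genes, which are not independent). Female-higher Z genes, 14 in number, moved in 11 cases. Part of the EE2 response lay outside these genes. Of the 1669 genes called with EE2 in males, 996 were sex-biased in vehicles and 673 were not. Among those 673, 290 also differed from vehicle females.

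On the axis from vehicle males (0) to vehicle females (1), EE2 males had a median position of 0.67 (0.26 to 0.87; mean 0.63 ± 0.17 SD, n = 17) over 1396 autosomal genes. Vehicle males lay at -0.01 to 0.1, vehicle females at 0.85 to 1.02 and EE2 females at 0.98 to 1.05. EE2 males with CH had a median of 0.79 and the others one of 0.58. Over 128 Z genes EE2 males lay at 0.39 (0.14 to 0.5), and the autosomal position was above the Z position in 17 of 17 libraries, by 0.247 ± 0.088 (exact sign-flip test, p = 1.53e-05, the smallest it can give). The gap was 0.299 ± 0.098 in the 7 CH libraries and 0.21 ± 0.06 in the 10 others. The sign-flip test covers the spread among EE2 males only. It leaves out the error of the axes, which rest on the same vehicle libraries throughout. With the vehicle males split so that the axis and the gene choice used different animals, the median position was 0.65 (0.58 to 0.70 over 10 splits).

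**Figure D2:**
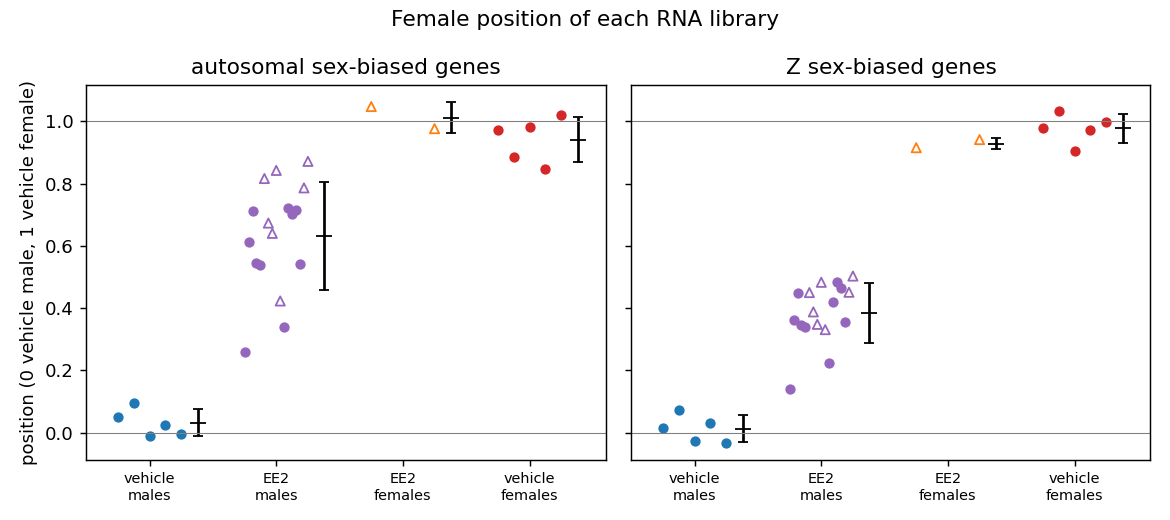
Female position of each RNA library (y axes; 0 is the vehicle male mean, 1 the vehicle female mean) by group (x axes), from sex-biased autosomal genes and from sex-biased genes on Z. EE2 males have a median of 0.67 on autosomal genes and 0.39 on Z genes.

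Z genes as a class were more abundant in males with or without EE2. Vehicle males against vehicle females had a median log2 difference of 0.646 over 176 Z genes (114 called higher and 14 lower), and the median of Z minus autosomes was 0.638 (exact permutation p = 0.00794, the smallest possible). EE2 males against vehicle females had 0.611 for Z (118 higher and 6 lower), and a per-library index, the level of Z genes minus that of autosomal genes, differed by 0.601 (exact permutation p = 3.8e-05 over 26334 splits, the smallest possible). EE2 males and vehicle males had an index difference of 0 (exact permutation p = 0.99). That 0 averages over the prefix. The index was 0.303 to 0.373 in the 10 EE2 males without CH and 0.213 to 0.291 in the 7 with CH. Vehicle males lay at 0.285 to 0.328, so an unchanged Z level cannot be read from the pooled value.

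The sex difference and the EE2 change in males share the vehicle males. Across genes, the correlation of the female-minus-male difference with the EE2 change was 0.839, against 0.617 in simulations without effects (genes are not independent replicates), and the covariance 0.428 against 0.034. With split controls the correlation was 0.763 (0.705 to 0.809) and the covariance 0.407 (0.382 to 0.427). Genes called in both comparisons toward the female level numbered 442 higher and 531 lower, against 131 and 187 for independent lists. With split controls they numbered 221 and 270, against 49 and 70.

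In genetic females the EE2 group holds 2 libraries. ELAVL4, a neuronal RNA-binding protein, stood at 283 ± 16 normalized CPM in EE2 females (SD, n = 2) and 91.7 ± 51.4 in vehicle females (SD, n = 5), a log2 difference of 1.83 (adjusted p = 0.041). The polysialyltransferase ST8SIA2 also rose, as did the growth cone protein DPYSL2 (1.30) and the neuronal ubiquitin hydrolase UCHL1 (1.12). The sex genes did not pass: CYP19A1 had -0.43 (adjusted p = 0.73), FOXL2 0.06, SOX9 0.01, AMH -0.40, DMRT1 0.08, ESR1 -0.42 and DDX4 0.55, with adjusted p-values of 0.32 to 0.99. A total of 152 genes were called, 74 higher and 78 lower (69 and 118 after quantile normalization). With 1 EE2 female left, assumed to vary like the other groups, limma called 0 genes without EE2 female 1 or without EE2 female 2, and 63, 13 and 8 genes were called without vehicle female 2, 3 or 4. The prefix as a covariate also left 0 limma calls.

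Other named rises in EE2 females were GNAI3 (1.91), a G protein subunit, the coenzyme Q gene COQ9 (1.16), and ACO1 (1.14) and the matrix link protein HAPLN1 (1.11), both on Z. The falls were led by PLDN (-1.63), TTC14 (-1.60), the calcium pump regulator PLN (-1.59), the actin nucleation gene ARPC1B (-1.53), FCRL2 (-1.46), FAM206A (-1.40), PDE6C (-1.39) and the checkpoint kinase CHEK2 (-1.37). Neural genes had 1 of 8 called (6 over the list alone), with a median of 1.68 (adjusted p = 0.00603; adjusted p = 0.937 with an estimated correlation). Proliferation genes had 2 of 16 called (4 over the list alone, adjusted p = 0.0277; adjusted p = 0.937 with an estimated correlation), CCNA2 (0.67) and the replication clamp PCNA (0.61). Among the other lists LEF1 of the Wnt pathway was called at -0.74 and XBP1 at -0.56. Adrenal genes had a median of 1.96 with 0 called (adjusted p = 0.475), with TH at 635 ± 118 normalized CPM in EE2 females and 151 ± 135 in vehicle females. Median, mean and test differed in sign for testis, germ cell, steroidogenesis, hedgehog, TGF-beta, Wnt, surface epithelium, immune, endothelial and muscle genes. None of the 20 named genes called in this comparison passed without EE2 female 1 (adjusted p = 0.2 to 0.3), EE2 female 2 (0.23 to 0.34), vehicle female 3 (0.055 to 0.088) or vehicle female 4 (0.059 to 0.099). Without vehicle female 2, 1 or 5, 15, 2 and 3 of them did not pass (adjusted p = 0.05 to 0.072).

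The EE2 effect itself differed between the sexes for 434 genes, 184 with a higher and 250 with a lower effect in males (185 and 148 after quantile normalization). CYP19A1 differed by 7.64 (SE 0.86, adjusted p = 2.9e-06), CALB1 (5.35), EMB (4.94), the lipolysis inhibitor G0S2 (4.20), PTPRZ1 (4.06) and the transglutaminase TGM4 (3.93), all called whichever library was left out. Further named genes were called in the pooled fit, but lost their call without EE2 female 2. They were the axon guidance gene NTN1 (5.63; without that library 4.88, adjusted p = 0.051), ISG12-2 (4.18; 3.61, adjusted p = 0.16), ESR1 (1.57; 1.28, adjusted p = 0.11), MNR2 (-2.91; -2.56, adjusted p = 0.17), KIAA1024 (-2.72; -2.70, adjusted p = 0.11), TAGLN (-2.67; -2.88, adjusted p = 0.14), the urokinase PLAU (-2.65; -2.86, adjusted p = 0.057) and ALDH1A1 (-2.46; -3.11, adjusted p = 0.085). Without EE2 female 1, PLAU (-2.43, adjusted p = 0.056), KIAA1024 (-2.74, adjusted p = 0.055), TAGLN (-2.46, adjusted p = 0.13) and ALDH1A1 (-1.81, adjusted p = 0.22) also lost it, as did TAGLN without vehicle female 4 (-2.50, adjusted p = 0.055) and ALDH1A1 without vehicle female 2 (-2.24, adjusted p = 0.058) or 5 (-2.33, adjusted p = 0.05). KCNMB1 (-2.58) lost it without any of the 12 vehicle or EE2 female libraries (-2.45 to -2.63, adjusted p = 0.05 to 0.21). The difference did not pass for SOX9 (-1.30, adjusted p = 0.11), AMH (-0.47, adjusted p = 0.67), DMRT1 (-0.30, adjusted p = 0.64) or DDX4 (0.60, adjusted p = 0.53). The count was 208 without EE2 female 1 and 44 without EE2 female 2.

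Feminization score 2 against score 1 gave no called gene in EE2 males. With limma 0 of 4448 genes passed and 93 had an unadjusted p under 0.05, and edgeR and DESeq2 also called 0. CYP19A1 had a difference of 0.47 (SE 0.43), FOXL2 0.27, AMH -0.37, SOX9 -0.22, ESR1 0.10, DDX4 -0.06 and DMRT1 0.01, each with an adjusted p of 1. The mean female position was higher by 0.062 in score 2 (exact permutation p = 0.483 over 19448 splits), by 0.071 without CH libraries (exact permutation p = 0.5) and by 0.15 within CH (exact permutation p = 0.333). Of the lists erythroid genes were called with 0 called members (median 0.48, adjusted p = 0.000228; adjusted p = 0.818 with an estimated correlation).

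Repeat RNA differed between the sexes for 86.6% of tested copies on W, 7.72% on Z and 3.32% on autosomes. Copies on the female-specific W chromosome were lower in vehicle males for 2798 of 3231 tested copies, with a median log2 of -3.81, and none was higher. They made up 9.09 ± 0.727% of repeat reads in vehicle females (SD, n = 5), 7.66 ± 0.169% in EE2 females (n = 2), 0.411 ± 0.0393% in vehicle males (n = 5) and 0.53 ± 0.083% in EE2 males (n = 17). The share in EE2 males was above that of vehicle males by 0.12 percentage points (exact permutation p = 0.00623), and by 0.069 without CH libraries (0.479 ± 0.0444%, n = 10, exact permutation p = 0.00799). It was below that of vehicle females (-8.558, exact permutation p = 3.8e-05, the smallest possible). Males are ZZ, so their reads at W copies, and the rise with EE2, cannot be transcripts of a W of their own. Named W copies were the endogenous retroviral pieces GGLTR12A at 3717625-3718360 (641 ± 85.5 normalized counts in vehicle females and 0.747 in vehicle males, log2 -9.42), GGERV28_I-int at 6639510-6640206 (-8.96), GGLTR3F1 at 2455014-2455485 (-8.81) and GGLTR7-int at 6637442-6637792 (-8.75). All repeat positions are as deposited, with sequence names of GRCg6a, and values of single copies are uncertain where near-identical copies share reads. In all 8252 copies differed between vehicle sexes, 2837 higher and 5415 lower in males, with 1822 and 2441 on autosomes and 1008 and 154 on Z. Without vehicle male 1 there were 1718 higher and 6377 lower copies. The autosomal GGERV28_I-int copy at 11:586813-588791 was higher in males by 5.37 (67.2 against 2.68). The male-higher (ATT)n copy at 22:1314132-1314186, CR1-E at Z:64959625-64960272 and CR1-Y3 at Z:64962715-64962971 had 1 or 2 reads over all vehicle females, and GGERV28_I-int at Z:77606163-77608141 had 0, so no folds are given.

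A retroviral cluster on chromosome 4 rose with EE2 in males to the level of females. On chromosome 4, between 85931183 and 85936719, 4 neighbouring copies of GGLTR11-int and GGERVL-A-int summed to 75.7 ± 42.7 normalized counts in vehicle males, 2860 ± 676 in EE2 males (1510 to 3780), 2860 ± 245 in vehicle females and 3040 ± 117 in EE2 females. The copy at 85935604-85935761 rose by 6.02 (SE 0.18, adjusted p = 1.2e-32) and that at 85935830-85936719 by 5.26 (SE 0.2, adjusted p = 2.3e-28). The other named rises were the (A)n copy at 18:2095246-2095269 (5.29), and GGERVL-A-int at 4:85931183-85931267 and the GA-rich copy at 10:9678285-9678331, which had 1 and 2 reads over all vehicle males and get no fold. Falls were led by GGLTR5B at 1:158943939-158944474 (-3.21), GGLTR6 at 4:66942461-66942912 (-2.95) and simple repeats such as (GT)n at 4:1997844-1997879 (-2.88). In all 3443 copies were called in males, 2278 higher and 1165 lower; edgeR called 6060, of which 2952 were higher and 3108 lower. The count was 1793 without CH libraries (1516 shared), and 1951, 1675, 1483 and 1969 without vehicle male 2, 3, 4 or 5. Without vehicle male 1 there were 4309, 3763 higher and 546 lower, and with a pseudocount of 2 the balance turned (2123 higher and 2398 lower).

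**Figure D3:**
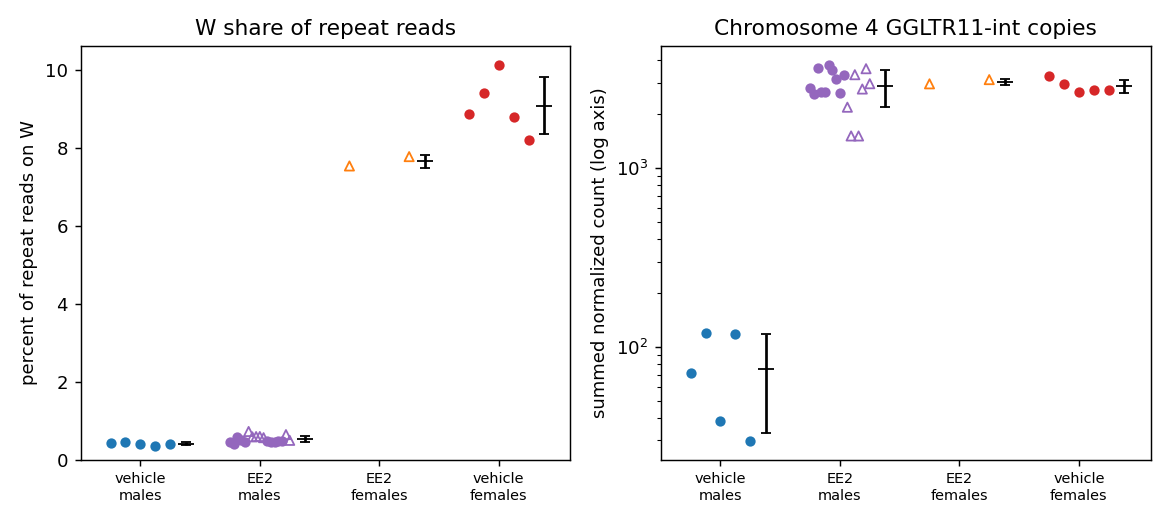
Percent of repeat reads on W copies per library, and summed normalized counts (log axis) of the 4 chromosome 4 copies per library, in the 4 groups of RNA libraries (x axes). EE2 males stay near vehicle males for W reads (0.53 against 0.411) and near vehicle females for the chromosome 4 copies (2860 and 2860).

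Of the sex-biased autosomal copies, 39.2% of 2441 female-higher and 27.1% of 1822 male-higher ones moved toward the female level in EE2 males. The share was 12.2% of 1008 male-higher Z copies and 1.61% of copies on W (45 of 2798), a chromosome that ZZ males do not hold. EE2 males against vehicle females had 6422 called copies, 2637 higher and 3785 lower, and 2831 of the lower ones lay on W. Among copies with a mean of at least 5 the balance turned (1911 higher and 1686 lower), and without vehicle female 3 there were 1626 higher and 3359 lower. The named higher copies included GGERV28_I-int at 33:326842-328819 (4.09) and the lower ones GGERVL18-int at W:5958526-5961824 (-9.03). EE2 females differed from vehicle females in 125 copies, 14 higher and 111 lower. edgeR called 38 (30 higher and 8 lower) and DESeq2 18 (14 higher and 4 lower), so the prevailing direction turned with the tool, and the limma count was 64 without vehicle female 4 and 63 without EE2 female 2. GGLTR7-int at W:1182447-1182724 was called at 3.92 by limma but not by DESeq2, and its neighbour at W:1182720-1183064 at 4.14 but not without EE2 female 1 (3.62, adjusted p = 0.08). Most other named copies of that comparison had 0 to 2 reads in either group. The score gave 0 called copies with limma, edgeR and DESeq2, with 9139 at an unadjusted p under 0.05 in limma.

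Captured methylated DNA gave called tiles between vehicle females and males after quantile normalization, most of them on Z. Males hold 2 Z chromosomes and females 1, so a higher Z signal in males does not by itself show denser methylation. The ratio of Z to autosomal windows above 0 was 0.593 ± 0.0371 in vehicle females (SD, n = 5), 0.751 ± 0.00865 in vehicle males (SD, n = 4), 0.604 ± 0.0182 in EE2 females (SD, n = 2) and 0.759 ± 0.0287 in EE2 males (SD, n = 18). Vehicle males were above vehicle females by 0.159 (exact permutation p = 0.00794), and EE2 males above vehicle females by 0.166 (exact permutation p = 2.97e-05), each the smallest p possible. EE2 males and vehicle males differed by 0.007 (exact permutation p = 0.63), a value that averages over the prefix. The ratio was 0.760 to 0.817 in the 8 EE2 males with CH and 0.713 to 0.778 in the 10 others. Vehicle males lay at 0.742 to 0.763. As deposited, limma called 0 of 499509 tiles in each of the 5 comparisons. At an unadjusted p under 0.05 there were 2457 tiles for the sex difference, 2147 for EE2 in males, 758 for EE2 in females, 4451 for EE2 males against vehicle females and 22347 for the score. Each count is below the share of 0.05 of tested tiles that would pass without any effect. The counts are thus no sign of weaker signal, and the fit as deposited does not keep its nominal rate. Without CH libraries the counts were 318 for EE2 in males, all lower with EE2, 83474 for EE2 males against vehicle females (13 higher and 83461 lower) and 17 for the score. With the prefix as a covariate they were 87852 (30 higher), 308019 (61 higher) and 0, with 1039 for EE2 in females (all lower) and 1 for the sex difference. The share of windows above 0 varied with the prefix: 40.5 ± 3.01% in the 8 CH and 16.0 ± 5.68% in the 10 other EE2 males, against 28.8 ± 8.04% in vehicle males, 31.4 ± 3.73% in vehicle females and 35.3 ± 1.55% in EE2 females.

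After quantile normalization 32 tiles differed between vehicle sexes (22 higher and 10 lower in males; 19 without CH libraries), and 21 of the higher ones lay on Z. EE2 in males, EE2 in females and the score gave 0 called tiles with limma, with 39753, 23857 and 27192 at an unadjusted p under 0.05. The counts for EE2 in females and the score lie near the share of 0.05 that would pass without any effect. Without CH libraries EE2 in males gave 3 called tiles and the score 1. EE2 males against vehicle females gave 1970 (1853 higher and 117 lower), with 1033 autosomal and 820 Z tiles among the higher and 77 autosomal and 24 W tiles among the lower ones; without CH libraries there were 363 (277 higher and 86 lower). A stretch of Z between 27928001 and 27972000 held 12 of the called male-higher tiles. Its mean score was 0.551 ± 0.0712 in vehicle females, 0.732 ± 0.0608 in vehicle males, 0.645 ± 0.0491 in EE2 females and 0.753 ± 0.088 in EE2 males. The tiles were chosen on the vehicle libraries, so only a comparison of EE2 groups is free of that choice. EE2 males were above EE2 females, within CH alone, by 0.198 (exact permutation p = 0.0222 over 45 splits, the smallest possible). EE2 males minus vehicle males gave 0.021 (exact permutation p = 0.668), and -0.051 without CH libraries (exact permutation p = 0.0869). Relative to autosomal tiles the stretch lay at percentile 95.9 in vehicle females, 96.5 in EE2 females and 99.9 in both male groups. The 5 male-higher tiles with the smallest p all lay in it: Z:27928001-27929000 (log2 0.62), 27971001-27972000 (0.53), 27939001-27940000 (0.50), 27930001-27931000 (0.43, adjusted p = 7.09e-07) and 27954001-27955000 (0.39). What is annotated there is not given, since the build of these positions is not stated.

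**Figure D4:**
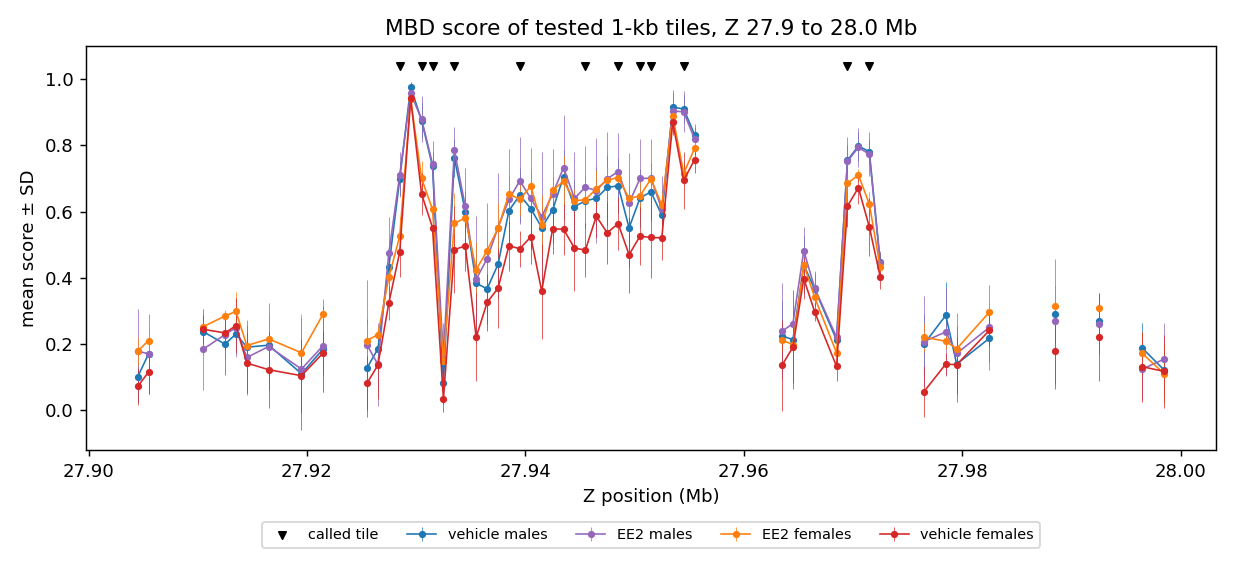
Mean score as deposited (y axis, ± SD) of each tested 1-kb tile against position on Z (x axis, 27900001 to 28000000) in the 4 groups of MBD libraries, with black triangles at the 12 tiles called between vehicle sexes after quantile normalization. Over the called tiles the male groups average 0.732 and 0.753 and the female groups 0.551 and 0.645.

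The 5 female-higher tiles with the smallest p were 1:165985001-165986000 (log2 -3.16, adjusted p = 0.0281), Z:73503001-73504000 (-2.23, adjusted p = 0.0389), 2:95626001-95627000 (-2.34, adjusted p = 0.0389), 19:1174001-1175000 (-2.05, adjusted p = 0.039) and 3:47606001-47607000 (-2, adjusted p = 0.0392). The first of these had a score of 0.432 in vehicle females, 0.598 in EE2 females, 0.029 in vehicle males and 0.0747 in EE2 males. Over the 6 female-higher autosomal tiles EE2 males stood, on the scores as deposited, 0.244 ± 0.332 of the way from vehicle males to vehicle females. Within EE2 males the CH libraries stood at 0.583 ± 0.1 (SD, n = 8) and the others at -0.027 ± 0.127 (SD, n = 10).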

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

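The tests of Z genes matched on size and expression, of the name prefix, of the Z stretch and the female-higher tiles of the MBD data, and the splits of the quantile-normalized MBD fits were chosen only after the results were seen, whereas the splits of the other fits were set beforehand.

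Of 68 groups of values tested, 9 held a library standing apart from its group, where about 3.4 would by chance. Gene reads stood apart in vehicle female 4 (10400000, group median 4860000), vehicle male 1 (46400000 against 5240000), EE2 male of score 1 number 6 (32300000 against 8480000) and EE2 male of score 2 number 6 (17200000 against 4870000). The Z position of EE2 male of score 1 number 1 was 0.141 (median 0.356), DMRT1 in vehicle female 5 was 2.54 normalized CPM (median 5.35), and DDX4 in EE2 male of score 2 number 2 was 257 (median 128). The W share of repeat reads was 0.646% in EE2 male of score 2 number 6 (median 0.49%), and 37.9% of MBD windows were above 0 in vehicle female 5 (median 29.7%).

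The EE2 effect differed between the sexes, by the test of the difference itself, for 434 genes. Those named by their size or beforehand were CYP19A1 (7.64), NTN1 (5.63), CALB1 (5.35), EMB (4.94), G0S2 (4.20), ISG12-2 (4.18), PTPRZ1 (4.06), TGM4 (3.93) and ESR1 (1.57) with higher effects in males, and MNR2 (-2.91), KIAA1024 (-2.72), TAGLN (-2.67), PLAU (-2.65), KCNMB1 (-2.58) and ALDH1A1 (-2.46) with lower ones. The EE2 females rest on 2 libraries, both with prefix CH. With the prefix as a covariate, whose effect is then read from EE2 males, the count was 468 (200 higher and 268 lower). It was 208 without EE2 female 1 and 44 without EE2 female 2, where the remaining EE2 female is assumed to vary like the other groups.

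Male-higher genes on Z moved toward the female level less often than autosomal ones (27.2% against 60.5%). If their sex differences were merely smaller or their expression lower, autosomal genes matched on both would move as rarely, but 69.3% of matched genes moved (61.4% to 77.2% over 10000 draws). A difference between name prefixes is argued against by the EE2 males without CH, in which the autosomal position was above the Z position by 0.21 (SD 0.06). Other technical causes were not tested. A candidate explanation, open and untested here, is that males keep a second Z chromosome whatever the state of the gonad.

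The male-higher MBD tiles of Z between 27900001 and 28000000 may follow the number of Z copies or the state of the gonad. The bin held 43 tiles with a mean score of at least 0.207. Over them vehicle males were above vehicle females by a median log2 of 0.392, inside the range of 660 other Z bins (0.105 to 0.74, percentile 47.9). Within CH, EE2 males were above EE2 females by 0.333, also inside the range of those bins (-0.005 to 0.654, percentile 63.2). Copy number alone could give both, but the other bins shared only the lower limit of the score and their ranges are wide. Lying inside them does not show that copy number suffices. The 12 called tiles gave 0.469 (0.264 to 0.731) between EE2 males and EE2 females of prefix CH. Z tiles matched on mean score gave 0.114 (0.047 to 0.158) and none of 10000 draws reached 0.469, so the called tiles exceeded Z tiles of like score. The called tiles were picked for their sex difference and are neighbours, while the drawn tiles were not. The draws therefore cannot settle whether copy number alone falls short there. The state of the gonad as the whole cause is argued against after quantile normalization, where the gap between EE2 males and EE2 females of prefix CH was 0.98 of the vehicle gap (SE 0.05) and EE2 males stood 0.02 (CH) and -0.04 (others) of the way to vehicle females, while the scores as deposited, which follow the share of windows, gave -0.62 (SE 0.3) and 0.28 (SE 0.15). A male-biased mark at these tiles stays a hypothesis, since the annotated sequence could not be looked up and collapsed repeats were not tested.

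The 6 female-higher autosomal MBD tiles could come from W sequence counted at autosomal positions or from the feminized state. The MBD table holds W only up to position 259700, with 112 tested tiles. In the repeat table, whose build may differ, a named W copy ends at 6640206. Much W sequence may thus have no W position of its own in the MBD table. On the scores as deposited, which do not compare directly between libraries, EE2 males without CH stood at -0.027, near vehicle males, which goes with the first. EE2 males with CH stood at 0.583, past the midpoint, which goes with the second. The tiles did not move together. EE2 males averaged 0.0672 and 0.0747 at the chromosome 1 tiles (vehicle females 0.399 and 0.432), and 0.107 and 0.144 on chromosomes 2 and 3 (0.361 and 0.277). They averaged 0.25 on chromosome 19 (0.319) and 0.196 on chromosome 7 (0.248), where EE2 females were lower (0.107). EE2 females, both CH, stood at 1.22 ± 0.082 (SD, n = 2), above the CH males. Prefix and the share of MBD windows above 0 go together (16.0% without and 40.5% with CH), so neither explanation can be told apart from a technical effect of the CH libraries.

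Other splits of the same libraries into groups of the same sizes were drawn 100 times, the real one included. For RNA genes the real split gave the highest count for the sex difference (1689, highest other 287) and EE2 in males (1669, highest other 924). It also did for EE2 males against vehicle females (1332, highest other 713). Each is 1 of 100, the smallest share these draws can give. In both EE2 comparisons the real split put all 7 CH libraries with the EE2 males, so the prefix may add to the counts. Without CH libraries 1708 and 1595 genes were called. The score gave 0 calls, which all 100 splits reached (highest other 184). For repeat copies the real split was also highest, with 8252 (highest other 3074), 3443 (399) and 6422 (3662), each 1 of 100. The 0 calls of the score (highest other 29) were reached by 100 of 100. As deposited, the MBD fits had 0 calls, so that all 100 splits gave as many, and single splits gave 1 call for the sex difference, 259755 for EE2 in males, 84307 for EE2 males against vehicle females and 127272 for the score. The split with 259755 and that with 84307 put all 8 CH males into the same group of 18. The real splits did so too and gave 0 calls, so that placement alone does not account for the counts. The split with 127272 put 6 of 8 into the smaller group, where the real split had 2, which goes with the prefix as a structure of these libraries. After quantile normalization the sex difference (32, highest other 9) was reached by 1 of 100 splits and EE2 males against vehicle females (1970) by 2. The other gave 4339 with all 8 CH males together, as in the real split. Within libraries without CH the count of that comparison was 363.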

How the results depend on the processing

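Alternatives chosen only after the data were seen were the prefix and the share of MBD windows as covariates, MBD scores without a log, no CH, 5-kb tiles or both combined with quantile normalization, MBD libraries under 15% of windows left out, positions from Z genes alone, the W share of repeat reads without CH, sums per repeat name, and other settings of the Z medians. Of 6072 values of 388 named features, 5376 kept direction and side of the threshold, 551 lost their call, 121 gained one and 24 changed sign. Where no cause is given, the cause was not tested.

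Counts of called genes ran from 1446 to 1603 with each library left out for the sex difference, 1365 to 1497 for EE2 in males, 0 to 143 for EE2 in females, 1024 to 1206 for EE2 males against vehicle females and 44 to 396 for the effect by sex. A 2-fold threshold, stricter by construction, left 561 (239 higher), 333 (241 higher), 40 (12 higher) and 174 (104 higher), so that the prevailing direction turned for the sex difference and EE2 in males. EE2 in females gave 879 (510 higher) with only the groups compared, 320 in DESeq2 (142 higher) and 0 with the prefix as a covariate. With an estimated correlation, which allows for genes moving together, 1, 1, 0, 0 and 0 lists were called, and 2 after quantile normalization for the sex difference. The position moved from 0.673 to 0.388 with Z genes alone, and the Z median of RNA from 0.638 to 0.608 with a pseudocount of 2.

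All 24 changes of sign were in values that had not passed the test. In EE2 females SOX9 was 0 with a pseudocount of 2, -0.05 after quantile normalization, -0.02 in DESeq2, and -0.22, -0.01 and -0.39 without vehicle female 3, vehicle female 4 or EE2 female 1 (range over left-out libraries -0.39 to 0.41). FOXL2 was -0.14 after quantile normalization, -0.72 with the prefix as a covariate, and -0.01, -0.07 and -0.25 without vehicle female 3, vehicle female 5 or EE2 female 2 (range -0.25 to 0.37). DMRT1 was -0.03 after quantile normalization and -0.12 without vehicle female 5 (range -0.12 to 0.15), AMH 0.24 with the prefix as a covariate and DDX4 -0.08 without EE2 female 1 (range -0.08 to 1.18). For the score DMRT1 was -0.03 after quantile normalization, -0.05 and -0.02 with the male of conflicting labels moved or left out, and -0.04 in edgeR and in DESeq2, and DDX4 was 0.08 without CH. ESR1 of EE2 males against vehicle females was 0.02 without CH and 0.02 with the prefix as a covariate, and DDX4 of the effect by sex was -0.03 without EE2 female 2 (range -0.03 to 1.23).

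Called repeat copies ran, with each library left out, from 7025 to 8095, 1483 to 4309, 63 to 197 and 4985 to 5771, in the order sex difference, EE2 in males, EE2 in females, EE2 males against vehicle females. A mean of at least 5 tests fewer copies and left 4888 for the sex difference and 3597 for EE2 males against vehicle females. For EE2 in females the count rose from 125 to 198, and EE2 in males kept its count within 1.5 times. No filter gave 2282 for EE2 in males and 1644 for EE2 in females. EE2 in males gave 1793 without CH, which has fewer libraries, 2134 with the prefix as a covariate and 6060 in edgeR. EE2 in females gave 359 and 199 with pseudocounts of 0.1 and 2, 72 with only the groups compared, 11 with the prefix as a covariate, 38 in edgeR and 18 in DESeq2. Sums per name gave 226, 159, 25, 200 and 0 after quantile normalization, 58 for EE2 males against vehicle females without W copies and 0 for the score without CH.

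MBD tiles as deposited had 0 calls in each comparison. Quantile normalization gave 32 for the sex difference and 1970 for EE2 males against vehicle females, and the share of windows as a covariate 9 and 116. EE2 males against vehicle females gave 5 with 4 times the pseudocount, 5 with a stricter filter on the tile mean, 59 with no filter, 35 without a log and 8 without the 4 libraries under 15% of windows. The sex difference gave 1 with no filter and 4 without a log, and EE2 in females 1 with no filter and 1 with 200-bp tiles. Without CH there were 318 for EE2 in males, 83474 for EE2 males against vehicle females and 17 for the score, and with quantile normalization as well 19, 3, 363 and 1. The prefix as a covariate gave 1, 87852, 1039 and 308019. With 5-kb tiles and quantile normalization there were 147, 116 and 2123, and 43, 0 and 1834 without CH as well. The Z median was 0.475 after quantile normalization. With each library left out EE2 males against vehicle females ran from 0 to 1 (1 without vehicle female 5), EE2 in females from 0 to 1 (1 without EE2 female 2) and the sex difference and EE2 in males from 0 to 0.

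Replicate numbers paired nothing in the MBD libraries, the only ones checked. There 19 same-number pairs had a mean correlation of -0.008 (-0.102 to 0.017) against 0.007 in 294 other pairs. In 7 of 38 tests of a library against another group, the library of its own number correlated best. With that number as a block the MBD fits called 16660, 80895 and 4090 tiles for EE2 in males, EE2 males against vehicle females and the score. MBD female positions from autosomal 1-kb tiles, alone, by score or against RNA, were not computed, since 0 autosomal tiles as deposited and 7 after quantile normalization differed by sex where 20 were needed. DESeq2 and edgeR were not run on MBD scores, which are not counts. The low recovery of 2-fold and 4-fold changes limits what 0 MBD calls can exclude.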

Other observations

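The sums per repeat name and the 5-kb MBD tiles were tests chosen only after the data were seen. Summed over all copies of a name, the retroviral GGLTR11-int stood at 4780 ± 334 normalized counts in vehicle females, 783 ± 250 in vehicle males, 5050 ± 63.4 in EE2 females and 3550 ± 570 in EE2 males (SD, n = 5, 5, 2 and 17). It rose in EE2 males by 2.21 (SE 0.13, adjusted p = 1.1e-23), and by 2.22 with W copies left out. That rise came from the chromosome 4 cluster: without the 3 GGLTR11-int copies of it, the other 566 went from 707 ± 249 in vehicle males to 824 ± 171 in EE2 males (0.25, SE 0.14, adjusted p = 0.42), against 2030 ± 347 in vehicle females. GGERVK1-int went from 1340 ± 456 in vehicle males to 3470 ± 990 in EE2 males, a rise of 1.40 (adjusted p = 9.8e-09), with 5840 ± 1930 in vehicle females, and 1.30 without CH libraries. The copy with most of that rise, at Z:70410456-70415717, held 11.2% of it, and one at 2:81985392-81990648 held 8.08%. The long terminal repeats GGLTR1 (0.77) and GGLTR3F1 (0.64) also rose. Of 54 names of endogenous retroviruses and their terminal repeats 33 were lower in vehicle males and 4 rose with EE2 in males, and with W copies left out 10 were lower and 1 higher in vehicle males. GGERVL-B-int, at -2.05 between vehicle sexes, had -0.59 with W copies left out (adjusted p = 0.057). GGLTR7-int, at -1.64 in EE2 males against vehicle females, had -0.01 without them.

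Some called copies lay in runs of neighbours. On Z, 45 neighbouring copies between 45210737 and 45367108 were higher in vehicle males (median log2 2.33). In EE2 males 45 copies at 1:172505167-172536928 (median 0.91), 25 at 4:83407888-83453236 (2.15) and 24 at 3:97307449-97393750 (2.94) rose, and 23 at 4:89350530-89390779 fell (-2.15). What genes lie there was not looked up, since no annotation of that build was used.

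In 5-kb MBD tiles with quantile normalization 116 tiles were higher in EE2 than in vehicle males, 111 of them autosomal, but limma called 0 without CH libraries (9628 at an unadjusted p under 0.05). Of the 147 tiles that differed between vehicle sexes, 17 were autosomal, 120 male-higher on Z, 3 female-higher on Z and 7 female-higher on W. Over all of them EE2 males had a median place of 0.10 with either prefix, vehicle males 0.14, vehicle females 0.80 and EE2 females 0.65. EE2 males are ZZ, so a place near vehicle males could follow from the Z and W copies alone. It cannot show whether autosomal methylation was feminized.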
